A study of Capra hircus with 6 samples.

How the data were processed

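RNA from goat adipose mesenchymal stem cells was sequenced in 6 libraries, 3 control and 3 with the label YAP overexpression. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with the VAHTS Universal V6 RNA-seq kit. The submitters' processing notes name fastp, HISAT2 and HTSeq, without versions, roles or settings. The genome build, the annotation, the strand setting and the treatment of reads that fit several genes are not given in the sources used here. The authors deposited FPKM values in 2 tables, one for each group, with the same 16285 gene identifiers in both. FPKM is a per-library scaling, no joint normalization of the libraries is recorded, and the same gene lengths made the recovered reads of both tables whole, so the groups were compared across the tables. The table with the YAP libraries held 6 further columns of per-sample values, named TAZ and pcDNA, whose names match no sample of the series, and these were not used. The name pcDNA is also that of a family of expression vectors, and the labels do not say what these columns hold. The controls compared here come from the other table, so table and group cannot be separated.

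Groups and replicate numbers were taken from the sample titles. Gene names were the symbols in the deposited tables, and 16262 of 16285 identifiers matched a symbol in the RefSeq gene table of assembly ARS1.2, which was used for names alone, so no coordinates are given. The other 23 identifiers appeared as dates in the deposited tables and were kept under the date with the gene description. List members without a matching symbol were not analysed here.

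Whole reads were recovered from the deposited FPKM values. In a library, the FPKM of a gene is a whole multiple of what 1 read is worth, so the steps between low values gave the relative depth, and the depth at which gene lengths became whole numbers gave each library's total. Reads were whole within 0.05 reads for 15957 of 15958 genes above 0 in any library and for 99.997% of values above 0, with a largest deviation of 0.001 reads among them. The implied totals were 34967990, 33871397 and 34594066 counted fragments in control replicates 1 to 3 and 36966875, 32593380 and 37131015 in YAP replicates 1 to 3. At the median gene length of 2851 bases, 3 reads, taken as the detection floor, correspond to 0.028 to 0.032 FPKM. No 2 libraries agreed within counting noise: the chi-square per gene between replicates ran from 7.69 to 30.7 over genes with at least 20 reads, so all 6 were kept as separate samples.

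FPKM values were compared as log2(FPKM + 1), a pseudocount of 1, for genes with at least 1 FPKM in at least 3 libraries (10761 genes). Linear models with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a trend of the prior variance on mean expression) gave log2 changes, standard errors and two-sided p-values, adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. The deposited FPKM were not rescaled. Confidence intervals are 95% intervals from the same model. For YAP1, WWTR1 and LATS2 an exact permutation test of group means was added. The model, gene lists and rule for named genes were fixed before the data were examined. In all, 29 gene lists were fixed, and the 24 with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, each adjusted over the lists. Camera compares a list with the other genes, so a list can pass while few of its members do. With an estimated correlation it takes its degrees of freedom from the libraries and not from the genes. A list that does not pass there may thus reflect the small number of libraries as well as correlated members. The text names YAP1, WWTR1 and LATS2, then the 8 largest rises and 8 largest falls among genes with a symbol, past the threshold, with a mean of at least 1 FPKM in the higher group and no overlap between groups, and then up to 4 members per list with the smallest adjusted p, or the member with the highest mean where none passed. Of the genes this rule takes, 2 are not reported here. Other genes are named where a count of 5 or fewer called for it or as low or untested markers, and were chosen after their values were seen.

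Alternatives were a pseudocount of 0.1, no filter on low values, a filter at 0.1 FPKM, median-of-ratios scaling, scaling to a fixed sum over the tested genes, quantile normalization, the replicate number as a block, no variance trend, library weights and leaving out each library in turn. A fit with limma-voom on the recovered reads and tests of KEGG pathways taken from the annotation in the deposited tables were added after seeing the data.

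The steps were tested on simulated data with known changes drawn from the real libraries' means and depths. All simulated genes shared 1 dispersion (0.0055) and were drawn independently, with as many rises as falls. The simulation held no shared replicate effect and no shift by abundant genes, so its error counts need not hold for the real libraries. In the simulated comparison of YAP overexpression with control, with 10719 genes tested, 97 of 98 tested genes changed by 1.5-fold and 97 of 97 changed by 2-fold were called in the right direction, and 15 unchanged genes were called. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9, and tables were handled with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.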

Results

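Gene expression was measured by RNA sequencing in goat (Capra hircus) adipose mesenchymal stem cells, stromal cells from fat that can be grown in culture and induced to form adipocytes. The 6 libraries fell into 2 groups of 3, control and YAP overexpression, and the labels of both groups recorded treatment for adipogenic differentiation. YAP (gene YAP1) and TAZ (gene WWTR1) are related coactivators held in check by the Hippo kinase cascade, in which LATS2 is a kinase that phosphorylates them. The values were FPKM, fragments per kilobase of gene model scaled to the library's counted fragments, for 16285 genes. They were normalised library by library and given in separate tables for the control and the YAP group, so that table and group coincide. Whole reads recovered from the steps between low FPKM values gave totals of 34967990, 33871397 and 34594066 counted fragments in control replicates 1 to 3 and 36966875, 32593380 and 37131015 in YAP replicates 1 to 3. Pearson correlations of log2(FPKM + 1) between libraries, taken across genes, which are not independent replicates, ran from 0.996 to 0.998 within groups and from 0.983 to 0.986 between groups. The labels did not say that replicates came from separate cultures or animals, so p-values measured only the spread between these samples, which may be technical. Levels below are mean FPKM ± SD (n = 3 per group), and log2 changes are on the log2(FPKM + 1) scale, which understates the change of genes with low values.

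The first comparison asked whether the gene named in the labels was raised. YAP1 stood at 27.2 ± 1.54 FPKM in control libraries and 27.4 ± 1.57 in the libraries labelled YAP, a log2 change of 0.01 (SE 0.08, 95% confidence interval -0.17 to 0.19, limma adjusted p = 0.95). An exact two-sided permutation test of the group means gave p = 1, where the smallest p that 3 against 3 libraries allow is 0.1, and 2 of the 3 libraries labelled YAP lay above the control mean. Each YAP1 value rested on 4280 to 5385 reads. The sign of this small difference changed when control replicate 1 (-0.03), YAP replicate 1 (-0.02) or YAP replicate 3 (-0.01) was left out. WWTR1 fell from 32.0 ± 3.38 to 21.4 ± 1.98 FPKM (log2 change -0.56, SE 0.10, limma adjusted p = 0.0013, exact permutation p = 0.1). LATS2 stood at 7.64 ± 0.62 FPKM in controls and 8.66 ± 0.09 in the libraries labelled YAP. It was not past the threshold (log2 change 0.16, SE 0.09, limma adjusted p = 0.17, exact permutation p = 0.1). The lowest LATS2 value in the libraries labelled YAP, 8.57 FPKM, lay above the highest control value, 8.19. After median-of-ratios scaling the LATS2 change was 0.24 with limma adjusted p = 0.0498, and with library weights 0.19 with limma adjusted p = 0.030. Because the YAP1 transcript was not higher in that group, it is called the libraries labelled YAP throughout, and every direction given below is that of the labelled group and not of a measured rise in YAP1.

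**Figure D1:**
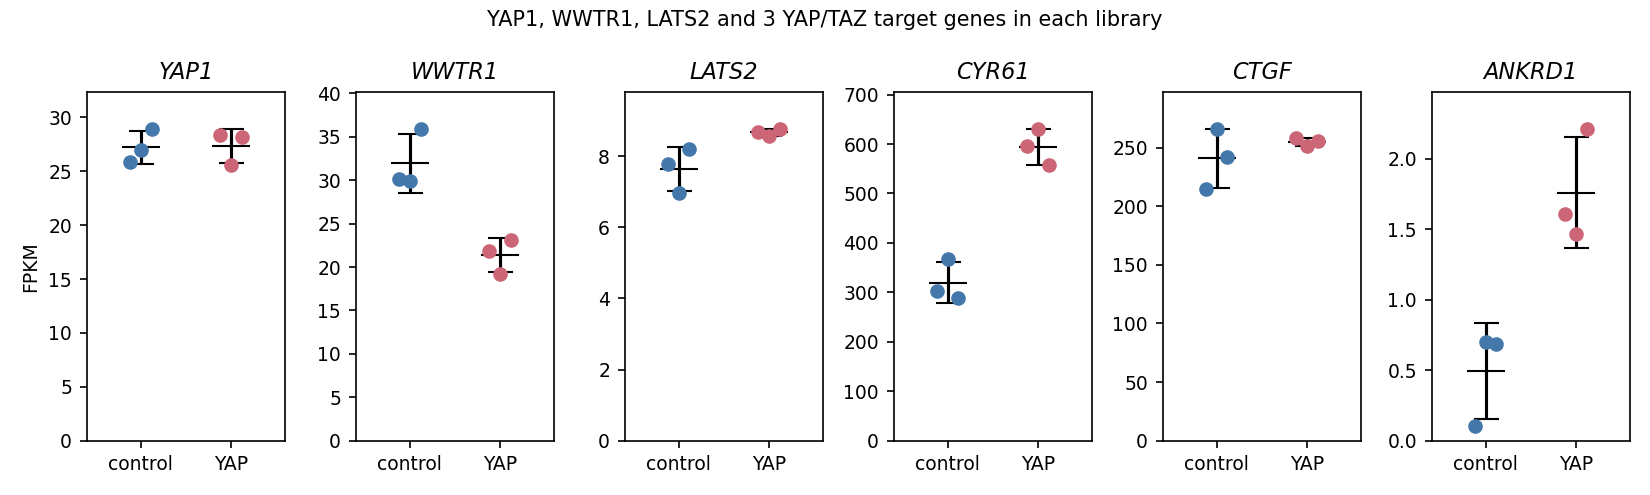
FPKM of YAP1, WWTR1, LATS2, CYR61, CTGF and ANKRD1 in each control library (blue points) and each library labelled YAP (red points), with the mean (wide bar) and SD (whiskers) of each group of 3 and axes that start at 0. The YAP1 means were 27.2 and 27.4 FPKM, while WWTR1 went from 32.0 to 21.4 and CYR61 from 320 to 595.

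Genes that YAP and TAZ are known to activate moved in both directions. Of 20 tested members of the list of conserved YAP/TAZ target genes, 7 rose and 3 fell (7 and 3 adjusted over the list alone). CYR61, a secreted matrix protein and classic YAP target, rose from 320 ± 41.9 to 595 ± 36.3 FPKM (log2 change 0.90, SE 0.10, limma adjusted p = 4.9e-05). F3, the initiator of coagulation, rose from 11.6 ± 2.48 to 20.4 ± 0.52 FPKM, and ANKRD1 rose from 0.49 ± 0.34 to 1.76 ± 0.39 FPKM. NT5E, which is also a stromal cell marker, fell from 170 ± 10.9 to 127 ± 6.38 FPKM. CTGF, named here outside the rule for named genes and after its values were seen, stood at 241 ± 25.3 and 255 ± 3.42 FPKM (limma adjusted p = 0.46). The list as a whole lay above other genes by camera (adjusted p = 0.027), with adjusted p = 0.26 with an estimated correlation and adjusted p = 0.068 when YAP replicate 3 was left out. Among 33 tested Hippo pathway components, 5 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.55), a balance that turned to 7 higher and 4 lower after median-of-ratios scaling. WWC1, a scaffold of the cascade, fell from 12.8 ± 1.71 to 5.36 ± 0.22 FPKM, whereas its relative WWC2 rose from 6.52 ± 0.45 to 11.6 ± 1.07. RASSF1 rose from 6.38 ± 0.67 to 10.7 ± 0.46 FPKM.

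The second comparison took all genes. Of 10761 genes tested, 3868 differed between the groups at limma adjusted p 0.05, with 1392 higher and 2476 lower in the libraries labelled YAP. A change of at least 2-fold was reached by 334 of them, 249 higher and 85 lower. The largest rises on the log2(FPKM + 1) scale were in genes of antiviral and inflammatory defence. MX2, an interferon-induced GTPase, rose from 0.53 ± 0.10 to 59.97 ± 10.9 FPKM, a 114-fold ratio (log2 change 5.31, SE 0.13, limma adjusted p = 5.7e-10). ISG15, an interferon-induced ubiquitin-like protein, rose from 5.25 ± 0.49 to 177 ± 47.0 FPKM (log2 change 4.80, SE 0.16). The chemokine CCL5 (log2 change 4.17), the cytokine IL6 (3.92), the complement genes C3 (3.86) and CFB (3.67), the GTPase MX1 (3.54) and the antiviral enzyme RSAD2 (3.36) followed. C3, the central component of complement, went from 8.36 ± 3.11 to 130 ± 11.8 FPKM.

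Among the genes that fell, ID1, a BMP-responsive inhibitor of basic helix-loop-helix factors, showed the largest change on the log2(FPKM + 1) scale, from 382 ± 82.6 to 61.7 ± 6.50 FPKM (log2 change -2.59, SE 0.14, limma adjusted p = 1.6e-07). PRSS35 fell from 30.8 ± 5.16 to 5.29 ± 0.47 FPKM, and the elongation factor gene EEF1A2 fell from 66.4 ± 3.97 to 15.1 ± 1.22. FST, which encodes the activin antagonist follistatin, fell from 51.1 ± 3.23 to 13.01 ± 0.86 FPKM. The integrin subunit gene ITGA6 fell from 22.9 ± 3.01 to 5.28 ± 0.17, and the chemokine receptor gene CXCR4 from 13.4 ± 0.71 to 2.98 ± 0.66. GZMA (log2 change -2.23) fell from 5.77 ± 0.95 to 0.44 ± 0.20 FPKM and TRPM2 (-2.03) from 7.36 ± 3.82 to 0.92 ± 0.12, which completed the 8 largest falls on that scale. As ratios of mean FPKM the falls of GZMA (13.2-fold) and TRPM2 (7.97-fold) were larger than that of ID1 (6.20-fold). Values of the 2 groups did not overlap in 97.2% of the 3868 genes and in 48.3% of all tested genes, where chance gives 10%. How reads that fit several related genes were counted is not given in the sources used here, so values of close relatives such as MX1 and MX2 carry that uncertainty. The excess of lower genes depended on scaling: 64.0% of calls were lower in the deposited FPKM and 47.0% after median-of-ratios scaling, with 3209 calls of which 53.04% were higher. Leaving out YAP replicate 1 reduced the count to 2411 genes. The count of genes changed at least 2-fold was 507 with a pseudocount of 0.1, of which 355 were higher and 152 lower.

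**Figure D2:**
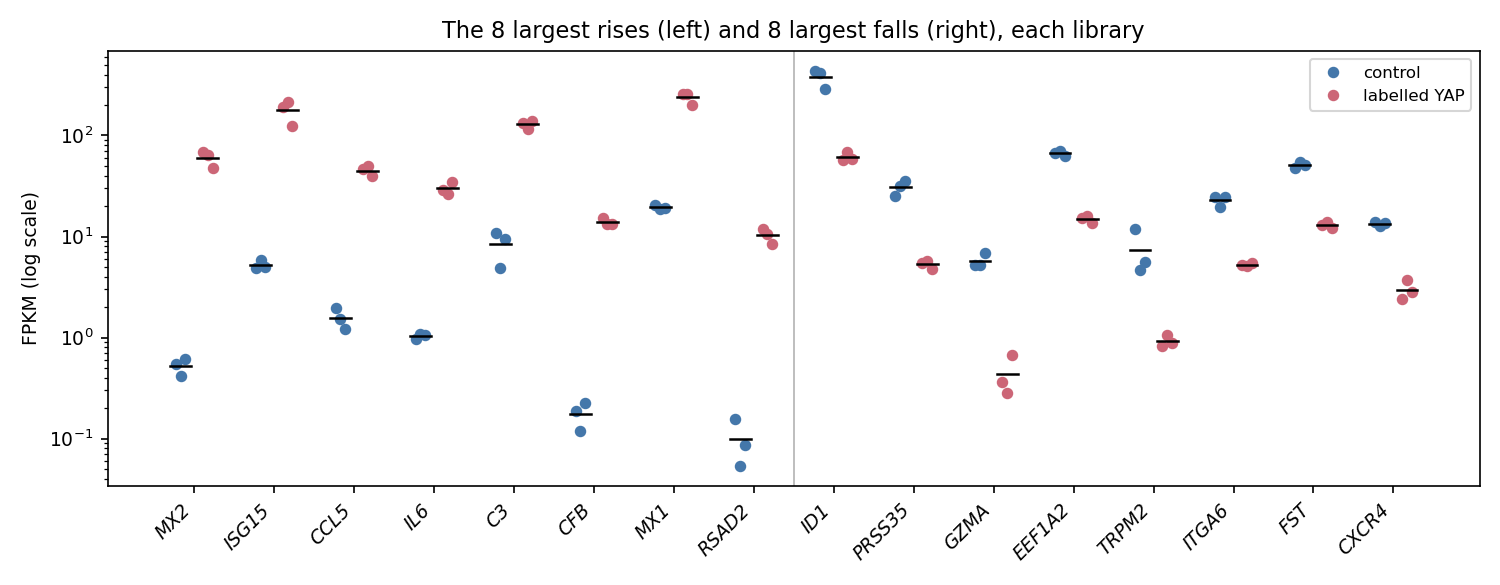
FPKM on a log axis of the 8 genes with the largest rise and the 8 with the largest fall in each control library (blue points) and each library labelled YAP (red points), with group means as bars. No overlap between the 3 values of each group was a condition for choosing these genes. MX2 stood at 0.53 against 59.97 FPKM and ID1 at 382 against 61.7 FPKM on average.

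Interferon response genes rose together. All 25 tested members were higher (25 adjusted over the list alone), with a median log2 change of 2.24 (camera adjusted p = 5.1e-36, and adjusted p = 0.11 with an estimated correlation). Beside MX1 and MX2, IFI6 rose from 48.5 ± 3.51 to 482 ± 67.0 FPKM and IFI44L rose from 1.02 ± 0.13 to 14.9 ± 1.31 FPKM. Of 18 tested NF-kB and inflammatory genes, 17 rose and 0 fell (17 and 0 adjusted over the list alone), with a median log2 change of 1.46 (camera adjusted p = 1.0e-19, and adjusted p = 0.11 with an estimated correlation). IL6 went from 1.03 ± 0.07 to 29.9 ± 3.95 FPKM. The adhesion molecule gene ICAM1 rose from 2.48 ± 0.36 to 32.3 ± 1.2 and PTGS2, which makes prostaglandins, from 20.7 ± 1.36 to 72.0 ± 7.97. LIF was the tested member that did not pass, at 2.51 ± 0.32 and 2.82 ± 0.29 FPKM (limma adjusted p = 0.36). Leukocyte markers stayed low in the same libraries: PTPRC had at most 1 read in any library, AIF1 had 0, CD74 at most 1 and TYROBP at most 3. Of the 3 leukocyte list members that were tested, CD14, a lipopolysaccharide coreceptor, rose from 9.58 ± 1.38 to 18.6 ± 0.17 FPKM. CD68 fell from 4.53 ± 0.44 to 2.03 ± 0.28, and LAPTM5 stood at 9.47 ± 0.23 and 10.2 ± 0.82 (1 and 1 adjusted over the list alone; camera adjusted p = 0.55).

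**Figure D3:**
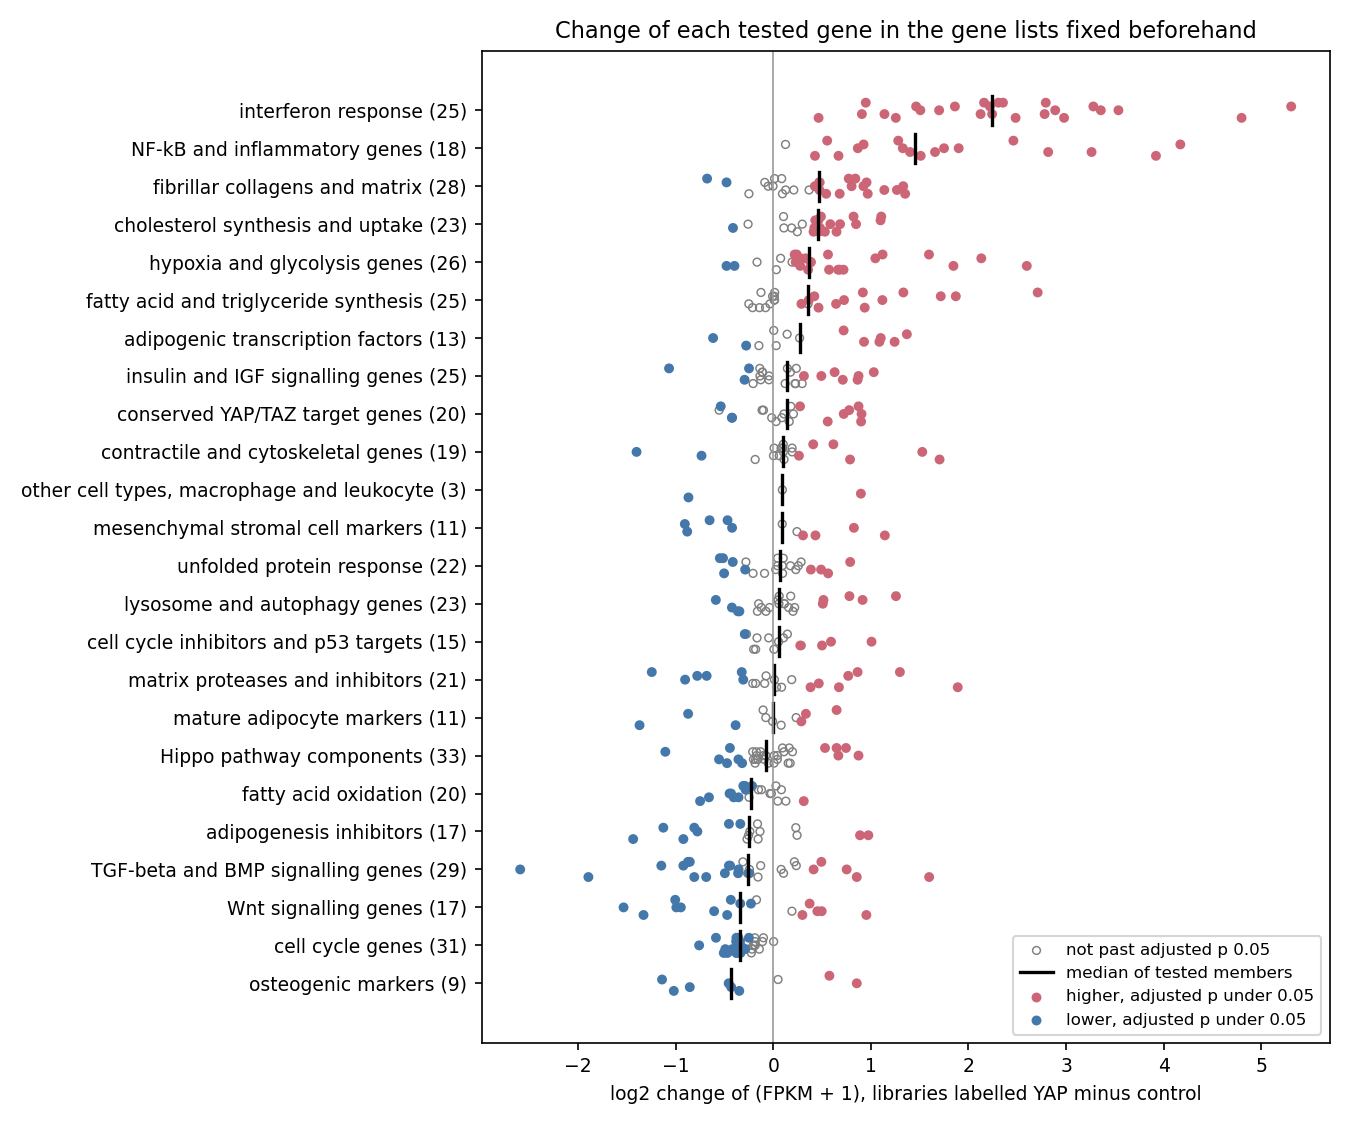
Log2 change of (FPKM + 1), libraries labelled YAP minus control, for each tested member of the 24 gene lists with at least 3 tested members (red, higher past adjusted p 0.05; blue, lower; open, not past), with list medians as black bars and the number tested in brackets. Interferon response (median 2.24) and NF-kB and inflammatory genes (median 1.46) lay farthest to the right.

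The labels recorded adipogenic differentiation in both groups, and several adipocyte genes had few reads in all 6 libraries. PPARG, the master regulator of adipogenesis, had 2 to 4 reads per library, the adipokine gene ADIPOQ 2 to 17, the lipase gene LPL 0 to 4, the lipid droplet gene PLIN1 12 to 27 and LEP 0 to 1. These genes were below the filter and were not tested, and floors and read numbers cover counting error only. Of 11 tested mature adipocyte markers, 3 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.77). FABP5, a fatty acid binding protein, fell from 42.3 ± 0.51 to 15.8 ± 0.84 FPKM (log2 change -1.37, SE 0.08, limma adjusted p = 1.7e-07). CIDEC, a lipid droplet protein, fell from 18.3 ± 1.31 to 9.56 ± 0.85, and BSCL2 fell from 25.3 ± 1.83 to 19.1 ± 0.93. LIPE, the hormone-sensitive lipase, rose from 1.01 ± 0.11 to 2.16 ± 0.16 FPKM. Of 13 tested adipogenic transcription factors, 6 rose and 2 fell (7 and 2 adjusted over the list alone; camera adjusted p = 8.2e-04, and adjusted p = 0.11 with an estimated correlation). After median-of-ratios scaling 7 rose and 1 fell. CEBPD, an early factor of adipogenesis, rose from 122 ± 11.2 to 263 ± 31.3 FPKM. EGR2 rose from 1.81 ± 0.19 to 5.64 ± 0.20, KLF9 from 3.87 ± 0.67 to 9.30 ± 0.62 and KLF4 from 19.4 ± 0.50 to 32.6 ± 1.59. Among 17 tested adipogenesis inhibitors, 2 rose and 7 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.11). Median-of-ratios scaling gave 3 higher and 5 lower. SOX9 fell from 2.96 ± 0.69 to 0.45 ± 0.08 FPKM, TGFB1 from 39.1 ± 3.69 to 21.9 ± 0.76 and ID2 from 61.5 ± 7.02 to 32.0 ± 3.71. WNT5A, in contrast, rose from 55.5 ± 7.69 to 109 ± 6.72.

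Of 25 tested genes of fatty acid and triglyceride synthesis, 13 rose and 0 fell (13 and 0 adjusted over the list alone; camera adjusted p = 5.2e-06, and adjusted p = 0.15 with an estimated correlation). The desaturase genes FADS2 and FADS1 rose from 12.3 ± 3.16 to 84.6 ± 1.5 FPKM (log2 change 2.71, SE 0.14, limma adjusted p = 8.7e-08) and from 19.9 ± 2.35 to 67.3 ± 1.93 FPKM. FASN, the fatty acid synthase, rose from 34.4 ± 4.74 to 75.4 ± 4.13 FPKM, and ACSS2, an acetyl-CoA synthetase, from 1.28 ± 0.16 to 4.76 ± 0.42. In the list of cholesterol synthesis and uptake, 16 of 23 rose and 1 fell (16 and 2 adjusted over the list alone; camera adjusted p = 5.9e-08, and adjusted p = 0.32 with an estimated correlation). INSIG1 rose from 29.0 ± 7.47 to 62.2 ± 7.47 FPKM, TM7SF2 from 4.01 ± 0.91 to 9.68 ± 0.39 and MVK, mevalonate kinase, from 14.6 ± 2.14 to 23.9 ± 1.28. Of 20 tested fatty acid oxidation genes, 1 rose and 10 fell (1 and 10 adjusted over the list alone; camera adjusted p = 0.10), and 6 fell after median-of-ratios scaling. CPT1A, which commits fatty acids to mitochondrial oxidation, fell from 37.0 ± 4.88 to 21.5 ± 1.40 FPKM. DECR1 fell from 5.42 ± 0.31 to 3.08 ± 0.42, HADHB from 55.2 ± 2.31 to 40.7 ± 0.90 and SLC25A20 from 15.3 ± 0.80 to 10.98 ± 0.66.

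Among fibrillar collagens and matrix genes, 16 of 28 rose and 2 fell (16 and 2 adjusted over the list alone; camera adjusted p = 1.3e-07, and adjusted p = 0.29 with an estimated correlation). DCN, the proteoglycan decorin, rose from 1430 ± 122 to 2767 ± 69.1 FPKM. THBS1 rose from 298 ± 40.0 to 721 ± 121, THBS2 from 118 ± 12.4 to 225 ± 8.16 and the crosslinking enzyme gene LOXL2 from 152 ± 20.6 to 335 ± 7.28. Matrix proteases and their inhibitors moved both ways, with 7 of 21 higher and 6 lower (7 and 8 adjusted over the list alone; camera adjusted p = 0.24). Median-of-ratios scaling gave 7 higher and 4 lower. The aggrecanase gene ADAMTS5 rose from 0.95 ± 0.13 to 6.26 ± 1.03 FPKM. The procollagen peptidase gene ADAMTS2 rose from 29.4 ± 1.58 to 50.8 ± 2.02 and the protease inhibitor gene SERPINE2 from 66.8 ± 8.42 to 165 ± 10.3. TIMP3, a metalloproteinase inhibitor, fell from 147 ± 12.3 to 61.3 ± 2.79. Of 19 contractile and cytoskeletal genes, 6 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p = 0.017, and adjusted p = 0.35 with an estimated correlation). CNN1, a smooth muscle calponin, rose from 24.4 ± 3.93 to 71.8 ± 2.79 FPKM and the myosin kinase gene MYLK from 4.47 ± 1.51 to 16.4 ± 2.34. FHL2 fell from 139 ± 13.9 to 52.1 ± 4.40 and the focal adhesion gene ZYX from 518 ± 57.1 to 311 ± 33.0.

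In the list of cell cycle genes, 0 of 31 rose and 19 fell (0 and 20 adjusted over the list alone; camera adjusted p = 1.8e-04, and adjusted p = 0.41 with an estimated correlation), and 13 fell after median-of-ratios scaling. CCNE2, a cyclin of the G1 to S transition, fell from 5.87 ± 0.92 to 3.04 ± 0.23 FPKM. The nucleotide synthesis genes RRM2 and TYMS fell from 108 ± 13.1 to 71.3 ± 5.90 and from 121 ± 7.46 to 93.0 ± 4.58. The replication clamp gene PCNA fell from 58.3 ± 3.15 to 45.7 ± 1.67. Of 15 cell cycle inhibitors and p53 targets, 4 rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.12). SESN2 rose from 10.8 ± 2.52 to 22.4 ± 0.26 FPKM. The death receptor gene FAS rose from 7.13 ± 0.19 to 10.5 ± 0.59 and CDKN1C from 1.58 ± 0.33 to 2.88 ± 0.36. CDKN2C fell from 18.1 ± 1.68 to 14.6 ± 0.56 FPKM (limma adjusted p = 0.023). This call was lost after median-of-ratios scaling (limma adjusted p = 0.090), 2 other scalings and 4 of the 6 fits without a library. Of 26 hypoxia and glycolysis genes, 20 rose and 2 fell (20 and 2 adjusted over the list alone; camera adjusted p = 3.9e-10, and adjusted p = 0.11 with an estimated correlation). The oxygen sensor gene EGLN3 rose from 1.23 ± 0.17 to 8.77 ± 0.54 FPKM (log2 change 2.13, SE 0.10). The mitophagy gene BNIP3 rose from 35.2 ± 1.68 to 108 ± 6.95, the glucose transporter gene SLC2A3 from 5.44 ± 0.87 to 38.5 ± 9.54 and ADM from 48.5 ± 8.11 to 176 ± 18.7.

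Signalling genes moved in mixed directions. Among 29 TGF-beta and BMP signalling genes, 5 rose and 14 fell (5 and 15 adjusted over the list alone; camera adjusted p = 0.11). Median-of-ratios scaling gave 5 higher and 11 lower. Beside ID1 and FST, the BMP antagonist gene GREM1 fell from 111 ± 7.32 to 49.5 ± 3.75 FPKM, and ID4 rose from 7.91 ± 1.13 to 26.0 ± 3.24. Of 17 Wnt signalling genes, 5 rose and 10 fell (5 and 11 adjusted over the list alone; camera adjusted p = 0.22). Median-of-ratios scaling gave 5 higher and 9 lower. The receptor gene FZD8 fell from 5.19 ± 0.87 to 1.13 ± 0.02 FPKM and cyclin D1 (CCND1) from 83.4 ± 13.7 to 32.3 ± 0.74. The transcription factor gene TCF7 fell from 3.04 ± 0.33 to 1.03 ± 0.15 and the Wnt deacylase gene NOTUM from 1.34 ± 0.21 to 0.17 ± 0.10. In the insulin and IGF signalling list, 7 of 25 rose and 3 fell (7 and 3 adjusted over the list alone; camera adjusted p = 0.027, and adjusted p = 0.35 with an estimated correlation). After median-of-ratios scaling 11 rose and 1 fell. IGF-binding proteins led it: IGFBP4 rose from 72.4 ± 3.45 to 149 ± 6.28 FPKM. IGFBP7 rose from 61.3 ± 6.70 to 101 ± 7.79 and IGFBP2 from 17.6 ± 5.11 to 32.2 ± 1.29, and IGFBP5 fell from 376 ± 26.9 to 179 ± 22.1. That list was not past the threshold without a filter (adjusted p = 0.19), with the 0.1 FPKM filter (adjusted p = 0.094), without control replicate 2 (adjusted p = 0.058) or without YAP replicate 3 (adjusted p = 0.075).

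Among 22 genes of the unfolded protein response, 4 rose and 5 fell (4 and 6 adjusted over the list alone; camera adjusted p = 0.45), and the balance turned to 5 higher and 4 lower after median-of-ratios scaling. The chaperone genes CALR and HSPA5 fell from 1451 ± 44.0 to 993 ± 34.4 FPKM and from 459 ± 24.8 to 323 ± 5.84 FPKM. MANF fell from 244 ± 16.8 to 170 ± 9.27, and HERPUD1 rose from 41.5 ± 5.27 to 61.5 ± 2.62. Of 23 lysosome and autophagy genes, 5 rose and 4 fell (7 and 4 adjusted over the list alone; camera adjusted p = 0.070). The autophagy gene WIPI1 rose from 37.0 ± 0.69 to 70.7 ± 2.72 FPKM. The cathepsin gene CTSL rose from 3.06 ± 0.60 to 8.65 ± 0.71 and the lysosomal lipase gene LIPA from 57.5 ± 3.71 to 99.3 ± 0.88. The cholesterol carrier gene NPC2 fell from 228 ± 16.0 to 151 ± 5.24.

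Markers of stromal identity and of other lineages gave the following. Of 11 mesenchymal stromal cell markers, 4 rose and 5 fell (4 and 5 adjusted over the list alone; camera adjusted p = 0.75). ENG fell from 150 ± 14.8 to 80.8 ± 4.98 FPKM and LY6E from 44.5 ± 3.39 to 23.3 ± 1.61. PDGFRB rose from 41.5 ± 3.44 to 74.3 ± 5.14 FPKM and DPP4 from 0.81 ± 0.28 to 2.96 ± 0.17. Of 9 osteogenic markers, 2 rose and 6 fell (2 and 6 adjusted over the list alone; camera adjusted p = 0.24). Median-of-ratios scaling gave 2 higher and 5 lower. BMP4 rose from 10.3 ± 0.80 to 19.5 ± 1.78 FPKM. DLX3 fell from 4.04 ± 0.87 to 1.28 ± 0.37, OMD from 1.45 ± 0.34 to 0.20 ± 0.06 and BMP2 from 2.20 ± 0.65 to 0.75 ± 0.14. The remaining lists had too few tested members for a list test. SOX9 was the 1 tested chondrogenic marker and fell, as did MSLN, the 1 tested epithelial and mesothelial marker, from 1.52 ± 0.23 to 0.66 ± 0.05 FPKM (each 1 lower adjusted over the list alone). Of 2 tested endothelial markers, ERG fell from 10.1 ± 0.52 to 6.80 ± 0.39 FPKM and EGFL7 stood at 18.3 ± 3.53 and 14.6 ± 2.11 (0 and 1 adjusted over the list alone). Of 2 tested pericyte and smooth muscle markers, CSPG4 fell from 25.7 ± 4.56 to 19.4 ± 1.27 FPKM (limma adjusted p = 0.024; 0 and 1 adjusted over the list alone). The CSPG4 call was lost after median-of-ratios scaling (limma adjusted p = 0.073), 2 other scalings, without a filter and in 3 of the 6 fits without a library. NOTCH3 stood at 12.5 ± 1.14 and 13.6 ± 0.52. No skeletal muscle marker was tested, and TNNT3, the highest of them, stood at 0.94 ± 0.21 and 0.36 ± 0.05 FPKM.

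By camera with a preset correlation, 11 of 24 lists differed from other genes, and with an estimated correlation 0 did after adjustment and 5 at an unadjusted p under 0.05. The small number of libraries limits the second form whatever the correlation. Interferon response, with all 25 tested members higher, had unadjusted camera p = 2.1e-37 with the preset and 0.0093 with an estimated correlation. By fry, which tests whether a list's genes move on balance in a direction without comparing them with other genes, 16 of 24 lists passed. Fry was run on the deposited FPKM alone, where the median log2 change of all tested genes was -0.10. That general shift, which depends on scaling, enters its results. Past fry but not camera were adipogenesis inhibitors, fatty acid oxidation, osteogenic markers and the Wnt and TGF-beta and BMP lists, all lower. The lists of cell cycle inhibitors and p53 targets and of lysosome and autophagy genes, both higher, also passed fry but not camera. Past camera but not fry were contractile and cytoskeletal genes (fry adjusted p = 0.086) and insulin and IGF signalling genes (fry adjusted p = 0.069). Other groupings of the 6 libraries into 3 and 3 put up to 13 lists past the camera threshold. Each of them mixes the groups unevenly and so keeps part of the real difference, so these numbers are not a chance level. For Hippo components, the unfolded protein response, mature adipocyte markers and mesenchymal stromal cell markers, the median, the mean and the camera and fry directions did not all have the same sign, and none of these 4 lists passed camera.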

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

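The fit to recovered reads was added after the data were seen, and the other settings were planned. Across 110 named genes, 1741 of 1760 comparisons of a gene under another setting kept direction and side of the threshold, 14 lost the call (CSPG4 and CDKN2C, 7 each), 2 gained it (LATS2) and 3 changed sign (YAP1). For the gene lists, 405 of 432 comparisons kept their side, 18 lost the call and 9 gained it. The count of 3868 changed genes was 3842 with a pseudocount of 0.1, 3819 without a filter, 4229 with the filter at 0.1 FPKM, 3209 after median-of-ratios scaling, 3171 scaled to a fixed sum, 3549 after quantile normalization, 3826 without the variance trend, 5746 with library weights and 3845 on recovered reads, of which 3723 were shared with the deposited FPKM. In these settings 0 calls changed sign. The lower share of calls was 47.0% after median-of-ratios scaling, 54.0% scaled to a fixed sum and 55.1% after quantile normalization, against 64.0%. Leaving out a library gave from 2411 (without YAP replicate 1) to 3606 genes (without control replicate 3), and the cause was not tested beyond the smaller number of samples. The count of genes changed at least 2-fold, 334, rose to 507 with a pseudocount of 0.1, because a smaller offset enlarges the changes of low genes. It was 532 (366 higher and 166 lower) on recovered reads, a fit that also differs in unit and weights, and the cause was not tested. All 334 were among both. YAP1 ranged from -0.028 (without control replicate 1) to 0.054 (without YAP replicate 2) on the log2 scale when a library was left out, with -0.018 without YAP replicate 1 and -0.014 without YAP replicate 3, and the cause was not tested. Of the list tests, 11 passed with the preset correlation and 0 with an estimated correlation (5 at an unadjusted p under 0.05), and fry passed 16. For YAP/TAZ targets and adipogenic transcription factors the estimates, 0.009 and -0.040, lay below the preset 0.01. Their unadjusted camera p still rose from 0.012 to 0.065 and from 2.7e-04 to 0.018. A higher correlation between members was thus not the cause in these lists. With an estimated correlation, camera also takes its degrees of freedom from the libraries and not from the genes. With so few libraries this raises p at any correlation, and its share of the rise was not tested. With the replicate number as a block, 5573 genes were called, all 3868 among them. Deviations of samples with the same number correlated at -0.018, 0.591 and 0.597 across genes. Those of samples with different numbers correlated at -0.6202 to 0.1435, and control replicate 1 correlated best with YAP replicate 2 (0.118). A shared effect of the replicate number was thus not excluded. The labels record no pairing, so the block was kept as an alternative only. The planned count-model tests were not run, because the deposited unit is FPKM. At 32593380 to 37131015 fragments per library, genes such as PPARG, with 2 to 4 reads per library, fell below the filter and were not tested in the main fit.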

Other observations

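The tests of pathways, swapped libraries, WWTR1, the target gene list, leukocyte markers, abundant genes and gene length were chosen after the results were seen. Pathways from the annotation in the deposited tables, tested with camera, included gene groups not covered by the fixed lists. The cell cycle, steroid biosynthesis and fatty acid degradation pathways are among those that overlap with those lists in subject. Others of that kind passed camera with the preset correlation, such as NF-kappa B (adjusted p = 0.0013) and HIF-1 signalling (adjusted p = 0.0055). Still others did not, such as glycolysis (adjusted p = 0.062), ECM-receptor interaction (0.082), TGF-beta (0.79) and Wnt signalling (0.82). Of 299 pathways with 10 to 300 tested genes, 48 passed with the preset correlation, 40 higher and 8 lower in the libraries labelled YAP, and with an estimated correlation 0 passed after adjustment and 23 at an unadjusted p under 0.05. RNA processing and ribosome production were on the lower side. In the spliceosome pathway 62 of 132 genes fell and 4 rose (37 and 4 after median-of-ratios scaling), in ribosome biogenesis 37 of 75 fell and 3 rose (26 and 4), in RNA transport 51 of 147 fell and 3 rose (28 and 5), and among RNA polymerase subunits 15 of 29 fell and 0 rose (9 and 1). In the cell cycle pathway 38 of 116 genes fell and 6 rose (26 and 8), and in fatty acid degradation, which did not pass (adjusted p = 0.99), 9 of 30 fell and 5 rose (5 and 7). On the higher side, 15 of 27 complement and coagulation genes rose and 7 fell, 10 of 17 steroid biosynthesis genes rose and 0 fell, 17 of 41 antigen processing genes rose and 9 fell, and 14 of 43 genes of RIG-I-like receptor signalling, which senses viral RNA in the cytoplasm, rose and 1 fell. With an estimated correlation the adjusted p was 0.61 for the spliceosome, 0.94 for the cell cycle, 0.64 for RNA polymerase, 0.72 for steroid biosynthesis, 0.63 for antigen processing and 0.59 for ribosome biogenesis, RNA transport, complement and RIG-I-like signalling.

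The libraries labelled YAP did not hold more YAP1 transcript than the controls, and the 95% confidence interval of the log2 change ended at 0.19. A swap of single libraries between the groups was argued against, since the lowest correlation within a group exceeded the highest between groups by 0.010. A counted WWTR1 transcript introduced in place of YAP1, a possible reading because the series text names TAZ in place of YAP for the cell line, was argued against as well, since the upper 95% bound of the WWTR1 change was -0.341. Whether YAP activity may have been raised without more counted YAP1 reads stayed open, since the target list passed with the preset correlation but had an unadjusted camera p = 0.065 with an estimated correlation. The estimate for that list, 0.009, lay close to the preset 0.01, so the higher p did not come from correlated members. That form of camera takes its degrees of freedom from the few libraries, which raises p at any correlation, so this p does not decide the question. A construct whose reads are not counted for YAP1, and a wrong label of the whole group, were not tested, and the columns named TAZ and pcDNA in the table of these libraries, which match no sample of the series, were not used here.

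Interferon and inflammatory genes were higher in the libraries labelled YAP. Leukocytes in those libraries were argued against, since PTPRC, CD74, TYROBP and AIF1 reached at most 0.158 FPKM in any library. Of the 3 tested members of the leukocyte list, CD14 rose, CD68 fell and LAPTM5 was not past the threshold. The log offset was argued against, since 100% of the called interferon genes were also called higher on recovered reads. That fit used the same library totals as the FPKM values, so it does not bear on depth scaling. After median-of-ratios scaling, which uses other factors, 25 of 25 tested interferon genes were called higher. A response to introduced nucleic acid and not to YAP cannot be told apart from the labelled treatment, since 0 of the control labels record an empty vector and the columns named pcDNA, which no label describes, were not used here. A biological effect of the labelled overexpression stayed open with it, and may or may not involve YAP, whose transcript was not higher.

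More genes were lower than higher in the libraries labelled YAP, 64.0% against 36.0% of calls. Scaling of FPKM by a few abundant genes may account for this balance: the 10 genes with the most reads held 15% of counted fragments in those libraries and 11.99% in controls on average, and with them left out of each library's total the lower share was 54.4%. With the 100 genes with the most reads left out it was 50.8%, and the median log2 change of all tested genes was -0.05 and -0.04 in these fits, against -0.10. Median-of-ratios scaling, which gave 47.0%, centres the genes itself and does not bear on the cause. Gene length as the sole cause was argued against, since the lower share was at least 59.5% in each of 3 length classes. The share was 67.4% in the short, 64.4% in the middle and 59.5% in the long class, so a partial contribution of length was not excluded. A change in total RNA per cell was not tested.

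The 6 libraries allow 10 groupings into 3 and 3, too few for a share under 0.05. The real grouping gave 3868 changed genes and the highest other gave 0, so 1 grouping reached that number, and for changes of at least 2-fold the values were 334 and 0, again reached by 1. For gene lists past the camera threshold the real grouping gave 11 and the highest other 13, and 3 of the 10 gave at least as many. Every other grouping mixes the groups unevenly and keeps part of the real difference. The list numbers are therefore not a chance level and do not decide whether the lists differ.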
